A study of Drosophila melanogaster with 6 samples.

How the data were processed

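RNA was sequenced from midguts of *Drosophila melanogaster* in 2 groups of 3 libraries. Per the labels, poly(A) RNA was taken from 2 µg of total RNA, fragmented and copied with random primers, fragments of about 200 to 400 bp were selected and 13 cycles of PCR were run. The protocol does not mark strand, so overlapping and antisense genes cannot be told apart. The submitters' processing notes name CASAVA 1.7.0 and 1.8.0, TopHat 1.4.1, HTSeq 0.5.3p3, DESeq 1.6.1 and the builds BDGP5 and mm9, with no role or order. All genes of the deposited table have fly gene IDs.

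The deposited signal, named normalised counts, was taken to be the gene read count divided by a size factor per library. The table held 13053 genes, 214 of them at 0 in all libraries. Of the values, 100% were whole multiples of the smallest non-zero value of their library within 0.001, from which reads were recovered. Size factors were 1.42, 1.41 and 1.46 in sucrose libraries 1, 2 and 3 and 0.947, 1.07 and 0.997 in Serratia libraries 1, 2 and 3. A count of 3 reads corresponds to 2.05 to 3.17 normalised read counts, which covers counting error only. Of the gene IDs, 12320 were in the current gene table, and names are those of the deposited table. Coordinates are not given because the annotation used here is of another build.

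Groups were taken from the sample titles. Genes with a mean of at least 10 normalised read counts over the 6 libraries (9303) were tested, two-sided, with limma 3.58.1 in R 4.3.3 on log2(value + 1), with an intensity trend and Benjamini-Hochberg adjustment at 0.05. Fold changes of low genes depend on that added count. With 3 against 3 libraries a two-sided exact permutation test cannot go below 0.1. Gene lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, adjusted over 38 lists, and with camera at an estimated correlation and fry. Of 1254 members written, 1233 were matched.

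The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 50 in the higher group and groups that do not overlap, up to 4 members with the smallest p per list (up to 2 where none was called), and *upd3*, *Dpt*, *PGRP-LB*, *puc*, *vn*, *GstD1*, *Hsp70Aa* and *Duox* in any case. All other genes named were chosen after their values were seen, among them *aay*, CG9826, *Thor*, the genes listed as kept in every fit without 1 library and the tissue transcripts.

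Alternatives were an added count of 0.5 or 5, no filter beyond 1 non-zero value or a mean of at least 50, TMM factors, quantile normalisation, the replicate number as a block, leaving out each library, limma without trend or with robust variances, and limma-voom, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads. Scaling by total reads and a fit with only sucrose library 3 were added after seeing the data. Replicates were compared before averaging, and all pairs within a group differed beyond sampling noise, with a chi-square per degree of freedom of 95.5 or more. Pearson correlations of log2 values were 0.955 to 0.974 between sucrose libraries, 0.933 to 0.960 between Serratia libraries and 0.925 to 0.967 across groups. The highest across groups was that of sucrose library 3 with Serratia library 2. The labels give no sequencing batch. CASAVA 1.7.0 and 1.8.0 are named without the libraries each was used for, so a batch by version could not be tested. Every sucrose library had more reads and a larger size factor than every Serratia library, so depth cannot be told apart from group.

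The steps were tested on simulated counts of 9303 genes, 200 of them changed, for this comparison of 3 against 3 libraries. limma recovered 31% of the genes changed 2-fold and 76% of those changed 4-fold, with 12 unchanged genes among 119 called. edgeR recovered 26% and 76%, with 11 unchanged among 113, and DESeq2 65% and 87%, with 45 unchanged among 201. camera recovered a list of 30 genes moved by 0.5 on the log2 scale and called 0 of 20 unmoved lists. The simulated genes were drawn independently, so false calls of lists of correlated genes were not tested.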

Results

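Midguts of *Drosophila melanogaster* of the strain wA5001 were compared after 3 h of feeding on 50 mM sucrose, alone or with *Serratia marcescens* Db11, an insect-pathogenic bacterium, at an OD of 10. Per the design text, crop and Malpighian tubules were not included. Each of the 2 groups, called sucrose and Serratia here, had 3 libraries, each from at least 10 midguts. Sucrose libraries 1, 2 and 3 held 29361072, 28917696 and 31116693 reads assigned to genes, and Serratia libraries 1, 2 and 3 held 26224393, 24215724 and 24875142. Values are read counts divided by the authors' size factor for each library, called normalised read counts. The labels do not say that replicates came from separate cultures or cohorts of flies, so p-values rest on the spread between these libraries, which may be partly technical.

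The comparison asked which midgut transcripts differed after 3 h of feeding on sucrose with *Serratia*. No group was fed killed or harmless bacteria, so infection and a meal of bacteria cannot be told apart. *Pepck* (FBgn0003067), for an enzyme of gluconeogenesis, rose from 1448 ± 259 to 7902 ± 443 normalised read counts (SD, n = 3 each), a log2 fold change of 2.46 ± 0.17 (SE) with a limma adjusted p of 0.00377. The phosphoserine phosphatase gene *aay* (FBgn0023129) rose by 3.07 ± 0.27 (log2, SE) and CG9826 (FBgn0034784) by 3.35 ± 0.18. The insulin receptor gene *InR* (FBgn0013984) fell by 1.53 ± 0.22 (log2, SE, limma adjusted p = 0.0345), though no fit without 1 library called it, with adjusted p values from 0.0587 without Serratia library 3 to 0.109 without Serratia library 2. Of 12 antimicrobial peptide genes limma and edgeR called 0, with 1 at an unadjusted p under 0.05, and DESeq2 called *AttB* higher.

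By limma, 88 of 9303 genes tested changed at an adjusted p under 0.05, 73 higher and 15 lower, and 81 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1899 genes. The groups did not overlap in any of the 88 genes, nor in 2696 of all tested genes, or 29%, against 10% by chance. On recovered reads DESeq2 called 855 genes, 525 higher and 330 lower, and limma without an intensity trend called 41. Scaling by total reads, chosen after seeing the data, gave 39 higher and 19 lower and moved the median of all genes by -0.27 on the log2 scale, so changes are relative to the authors' scaling. With this shift included the medians of 7 of the 38 gene lists, from 0.05 to 0.26 under the authors' scaling, were negative. With the shift removed 0 list medians changed sign. Without sucrose library 1, 2 or 3 the count was 27, 23 or 22, and without Serratia library 1, 2 or 3 it was 39, 17 or 88, with 31 of the last lower. All 88 genes kept their sign in these fits, which groups that do not overlap fix in advance. The call was kept in each of the 6 fits without 1 library for 13 genes, all higher. These were *aay*, *Adgf-A*, *Pepck*, *su(r)*, CG10654, CG3829, CG42542, CG4830, CG7460, CG8083, CG8785, CG9416 and CG9826.

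The 8 largest rises were those of CG13947 (FBgn0031277), *lcs* (FBgn0028583), *LysP* (FBgn0004429), CG32984 (FBgn0052984), CG8708 (FBgn0033271), CG10654 (FBgn0036294), CG17681 (FBgn0032668) and *Est-6* (FBgn0000592). CG10654, called in every fit without 1 library, rose from 14.2 ± 4.05 to 495 ± 99.0 normalised read counts (SD, n = 3 each, limma adjusted p = 0.0015). *lcs* rose from 152 ± 105 to 16180 ± 9204, or by 6.78 ± 0.69 on the log2 scale (SE, limma adjusted p = 0.0101). CG13947 had 16.9 normalised read counts in sucrose library 1 and 0 in sucrose libraries 2 and 3, against 1395 ± 343 in Serratia (SD, n = 3, limma adjusted p = 0.0179). The lysozyme gene *LysP*, known from salivary glands, stood at 11.9 ± 6.78 in sucrose (SD, n = 3) and at 3382, 1716 and 282 in Serratia libraries 1, 2 and 3. The carboxylesterase gene *Est-6* rose 16.1-fold. Without Serratia library 2 the adjusted p was 0.0558 for *lcs*, CG32984 and CG17681, 0.0974 for CG13947, 0.109 for *LysP*, 0.103 for CG8708 and 0.101 for *Est-6*. The calls of *LysP*, CG8708 and *Est-6* were kept only without Serratia library 3 and that of CG13947 only without sucrose library 1, with highest values in the other fits of 0.109, 0.103, 0.122 and 0.0974. The call of *lcs* also ended without Serratia library 1 (0.0532) and sucrose library 2 (0.0527), and that of CG17681 without sucrose library 3 (0.0517). limma-voom ended the calls of *LysP* (0.158), CG8708 (0.14), CG32984 (0.119) and *Est-6* (0.0661), limma without trend those of *LysP* and *Est-6* (0.0661 each), and the replicate block those of CG13947 and CG32984 (0.0515 each) and CG8708 (0.0598). Over all alternatives adjusted p values ran from 3.27e-10 to 0.434 for *LysP*, 7.40e-15 to 0.408 for CG8708, 1.08e-13 to 0.355 for CG32984, 1.18e-11 to 0.414 for *Est-6* and 0.000204 to 0.0974 for CG13947.

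The 8 largest falls were those of snoRNA:Psi28S-3342 (FBgn0086667), CG34040 (FBgn0054040), *tobi* (FBgn0261575), *Ugt86Dd* (FBgn0040256), CG18171 (FBgn0035262), *Fancl* (FBgn0037781), *InR* and *spel1* (FBgn0015546). The alpha-glucosidase gene *tobi* fell from 29637 ± 8840 to 5770 ± 2020 normalised read counts (SD, n = 3 each, limma adjusted p = 0.0301). *Fancl*, of the Fanconi anaemia pathway of DNA repair, fell from 1393 ± 361 to 428 ± 106, and *spel1*, for a mismatch repair protein, fell by 1.36 ± 0.17 (log2, SE). The snoRNA fell from 263 ± 145 to 4.09 ± 2.91, in poly(A)-selected and unstranded libraries in which its reads cannot be told apart from those of a host transcript. No fit without 1 library called CG18171 (up to 0.208, without sucrose library 2), *Fancl* (up to 0.112, without sucrose library 1) or *InR* (up to 0.109, without Serratia library 2). The calls of *tobi*, *spel1* and CG34040 were kept only without Serratia library 1, Serratia library 3 and sucrose library 2, with highest values of 0.125, 0.12 and 0.171, each without sucrose library 1. The call of the snoRNA ended without Serratia library 2 (0.0593), sucrose library 1 (0.0858) and sucrose library 2 (0.0851), and that of *Ugt86Dd* without Serratia library 2 (0.0558) and sucrose library 1 (0.0622). The replicate block ended the calls of *Fancl*, *InR*, *spel1*, *tobi*, *Ugt86Dd*, CG18171 and CG34040, limma without trend those of CG34040, *tobi*, CG18171, *Fancl* and *InR*, limma-voom those of the snoRNA, CG34040 and CG18171, and edgeR, another filter or scaling by total reads that of CG18171. The ovary transcript *osk* stood at 364, 863 and 2.0 normalised read counts in sucrose libraries 1, 2 and 3 and at 43.3, 0.9 and 0 in Serratia libraries 1, 2 and 3. With only sucrose library 3 as control, chosen after seeing the data and assuming that this library varies like those of the other group, limma called 1 gene higher and 0 lower, with 407 genes at an unadjusted p under 0.05, and DESeq2 and edgeR on all libraries called 330 and 10 lower. In that fit *tobi* had -2.54, *Fancl* -2.10, *spel1* -1.34 and *InR* -1.32 (log2), but the lower genes were called with this library among the 3, which fixes the sign of these values.

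**Figure D1:**
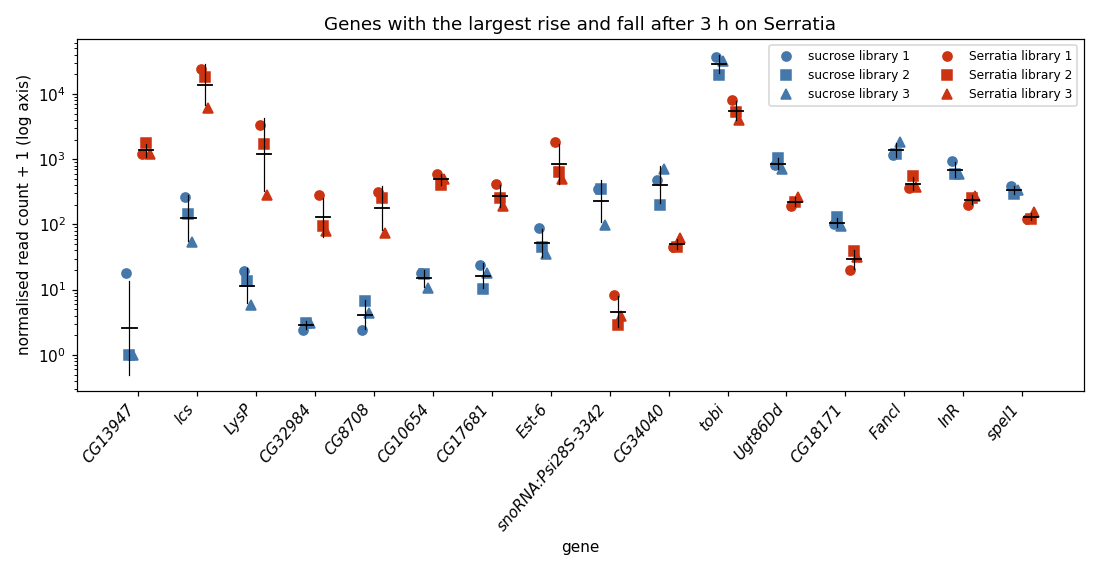
Normalised read counts plus 1 (log axis) of the 8 genes with the largest rise and the 8 with the largest fall, for each of the 3 sucrose and 3 Serratia libraries. Horizontal bars mark the mean and vertical lines the SD, both on the log2 scale, and *LysP* spreads from 282 to 3382 within Serratia.

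Of 32 genes of sugar metabolism and the insulin or FoxO response, 3 rose, 1 fell and 28 did not pass, and adjusted over the list alone 10 were higher and 3 lower, by limma. edgeR called 2 higher and 1 lower, and DESeq2 10 higher and 3 lower. Beside *Pepck*, the hexokinase gene *Hex-C* (FBgn0001187) rose by 1.53 ± 0.25 (log2, SE) and the sestrin gene *Sesn* (FBgn0034897) by 1.26 ± 0.18, and *InR* fell. The list passed camera with its preset correlation (median 0.34, adjusted p = 0.00202), with an adjusted p of 0.485 with an estimated correlation. No fit without 1 library called *Hex-C* (0.077 without Serratia library 3 to 0.176 without sucrose library 2) or *InR* (0.0587 without Serratia library 3 to 0.109 without Serratia library 2), and *Sesn* was called only without Serratia library 1 (up to 0.145, without sucrose library 2). *Hex-C* had an edgeR adjusted p of 0.0601, within a range of 1.31e-06 to 0.599 over its alternatives, and its call and those of *Sesn* and *InR* also ended by limma without trend and with the replicate block. Those of *Hex-C* and *Sesn* ended under scaling by total reads, and that of *Hex-C* by limma-voom. The translation repressor gene *Thor*, called by DESeq2, had -1.96 ± 0.44 (log2, SE, limma adjusted p = 0.0959). Of 24 carbohydrase genes *tobi* fell by limma and edgeR and 23 did not pass, adjusted over the list alone 5 were higher and 6 lower, and DESeq2 called 4 higher and 6 lower. *Mal-A1* had -1.38 ± 0.26 and CG9468 had 1.94 ± 0.38 (log2, SE), and DESeq2 called both. limma called *Mal-A1* under quantile normalisation (0.0127) and scaling by total reads (0.0284) and CG9468 with the replicate block (0.0414), within ranges of 7.33e-06 to 0.480 and 2.20e-05 to 0.447 over their alternatives. The list's camera adjusted p was 0.561. The call of *tobi* was kept only without Serratia library 1, with up to 0.125 without sucrose library 1, and it ended by limma without trend and with the block.

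Of 30 digestive serine protease genes 2 rose by limma and 28 did not pass, and adjusted over the list alone 10 were higher and 1 lower. edgeR called 2 higher, *Jon25Bii* and *Jon25Biii*, and DESeq2 called 12 higher and 1 lower. *Jon25Bii* (FBgn0031654) rose from 32834 ± 12598 to 156930 ± 44933 normalised read counts (SD, n = 3 each, limma adjusted p = 0.034), and *Jon25Bi* (FBgn0020906) rose by 2.24 ± 0.35 (log2, SE). Fold changes were positive for 28 members, with a median of 0.58, a camera adjusted p of 1.63e-06 and an adjusted p of 0.528 with an estimated correlation. The median was 0.25 under quantile normalisation and 0.32 under scaling by total reads. No fit without 1 library called *Jon25Bi* (0.061 without sucrose library 2 to 0.135 without sucrose library 3), *Jon25Bii* was called only without sucrose library 2 (up to 0.137, without sucrose library 1), and both calls ended under quantile normalisation (0.0743 and 0.0626, with ranges of 3.69e-08 to 0.480 and 1.56e-09 to 0.447 over their alternatives). Both calls also ended without the filter, by limma without trend and with the replicate block, and that of *Jon25Bi* by edgeR (0.0606), by limma-voom and under scaling by total reads. *Jon25Biii* had 1.06 ± 0.20 (log2, SE, limma adjusted p = 0.0734) and passed by edgeR (0.0461), with robust variances (0.0495) and at a mean of at least 50 (0.0371), within a range of 2.92e-09 to 0.987 over its alternatives. Reads may be shared among these similar neighbouring genes. Of 7 lysozyme genes *LysP* rose by limma, edgeR and DESeq2 and 6 did not pass, with 1 higher adjusted over the list alone. *LysB*, *LysE* and *LysC*, close paralogs with possibly shared reads, had log2 fold changes of 1.05, 0.96 and 0.80. The list's median was 0.96, or 0.53 without sucrose library 3 and 1.61 with only sucrose library 3 as control. Its camera adjusted p was 0.0154, and the adjusted p was 0.661 with an estimated correlation. Without Serratia library 2 the adjusted p of *LysP* was 0.109, and of the fits without 1 library only that without Serratia library 3 called it. Its call also ended by limma-voom and by limma without trend.

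Of 21 genes of peptidoglycan recognition and the Imd pathway 1 rose by limma and 20 did not pass, adjusted over the list alone 2 were higher, and edgeR called 0 and DESeq2 2 higher, with 4 at an unadjusted p under 0.05. *pirk* (FBgn0034647), a negative regulator of Imd signalling, rose from 1314 ± 631 to 6280 ± 1300 normalised read counts (SD, n = 3 each, limma adjusted p = 0.0438). Its edgeR adjusted p was 0.0697, within a range of 1.53e-07 to 0.172 over its alternatives, and no fit without 1 library called it (0.0511 without sucrose library 2 to 0.172 without sucrose library 1). It was not called by limma-voom, limma without trend, with the replicate block or under scaling by total reads either. The amidase gene *PGRP-LB* had 2399 ± 556 in sucrose and 6337 ± 2505 in Serratia (SD, n = 3 each, limma adjusted p = 0.0919). The list's camera adjusted p was 0.843, and its median of -0.04 and mean of 0.355 differed in sign. None of 12 antimicrobial peptide genes passed by limma or edgeR, 0 adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 1 higher by DESeq2, *AttB*. *Drs* had 3.33 ± 1.17, *AttB* 2.27 ± 1.06 and *Dpt* 0.14 ± 1.07 (log2, SE). *AttB* stood at 14.8, 3.75 and 78.2 normalised read counts in Serratia libraries 1, 2 and 3, and its log2 fold change was 1.21 without Serratia library 3, in which the cuticle gene *Lcp1* was high. Without sucrose library 1 or 3 *Drs* had 4.51 or 2.12, and *Dpt* had -0.91 without Serratia library 1 and -0.70 without sucrose library 3. That list's camera adjusted p was 0.235, and 0.0121 under scaling by total reads, within a range of 0.00282 to 0.888 over its alternatives. None of 20 Toll pathway genes passed by limma, edgeR or DESeq2, with 4 at an unadjusted p under 0.05 (camera adjusted p 0.818, *grass* 1.00 ± 0.29). Nor did any of 12 JAK-STAT and Turandot genes by these tools, with 0 at an unadjusted p under 0.05 (0.376, *upd3* -1.55 ± 0.87). In fits without 1 library *upd3* ran from -2.37 to -0.50 (log2). Without Serratia library 2 the camera adjusted p was 0.0331 for JAK-STAT genes, 0.0239 for JNK genes and 0.0173 for EGFR genes. With all libraries and an estimated correlation the camera adjusted p of these lists was 0.838, 0.709 and 0.832. None of 16 JNK and apoptosis genes passed by limma or edgeR (0.091, *W* -1.44 ± 0.25, *puc* -0.21 ± 0.17). In fits without 1 library *puc* ran from -0.33 to -0.06 (log2). Of the 16 genes 1 was higher and 1 lower adjusted over the list alone, and 8 were at an unadjusted p under 0.05. DESeq2 called 1 higher and 2 lower, *W* among them, and limma without Serratia library 3 called *W* (0.0385, within a range of 0.000296 to 0.955 over its alternatives), as did limma under quantile normalisation and scaling by total reads. None of 14 EGFR genes passed by limma or edgeR (0.179, *spi* -0.83 ± 0.24, *vn* -0.07 ± 0.42), with 3 at an unadjusted p under 0.05 and 2 lower by DESeq2, *spi* among them, and *vn* had 0.29 without Serratia library 1 and 0.15 without sucrose library 2. None of 16 Wnt, Hippo and Dpp genes passed by limma or edgeR (0.843), with 2 at an unadjusted p under 0.05 and *tkv* (-0.85 ± 0.17) lower adjusted over the list alone, by DESeq2, under quantile normalisation and under scaling by total reads.

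Of 31 UDP-glycosyltransferase genes 2 fell by limma and edgeR and 29 did not pass, adjusted over the list alone 1 was higher and 3 lower, and DESeq2 called 1 higher and 4 lower. *Ugt86Dd* fell from 857 ± 167 to 222 ± 35.5 normalised read counts (SD, n = 3 each, limma adjusted p = 0.0101), and its neighbouring paralog *Ugt86Dc* (FBgn0040257), with possibly shared reads, fell by 1.22 ± 0.20 (log2, SE). The call of *Ugt86Dd* ended without Serratia library 2 (0.0558) and sucrose library 1 (0.0622), and that of *Ugt86Dc* was kept only without sucrose library 2 (up to 0.208, without sucrose library 1). Both calls ended with the replicate block and that of *Ugt86Dc* by limma without trend. The list's camera adjusted p was 0.0241, with an adjusted p of 0.485 with an estimated correlation, and it was 0.0523 without Serratia library 2 and 0.104 without Serratia library 3. None of 67 cytochrome P450 genes passed by limma (*Cyp6v1* 0.73 ± 0.12, *Cyp4ac3* -1.09 ± 0.23), with 1 higher adjusted over the list alone and 19 at an unadjusted p under 0.05. edgeR called 1 higher, *Cyp6v1*, which limma also called at a mean of at least 50, and DESeq2 called 2 higher and 2 lower, with *Cyp6v1* and *Cyp4ac3* among them. Without Serratia library 3 limma called *Cyp4ac3* (0.043, within a range of 0.0018 to 0.987 over its alternatives). That list's median was -0.28, or -0.18 without Serratia library 2 and -0.15 with only sucrose library 3 as control, and its camera adjusted p 0.028, with an adjusted p of 0.661 with an estimated correlation, and it was 0.054 without sucrose library 1, 0.0816 without sucrose library 2 and 0.119 without Serratia library 2.

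None of 45 oxidative stress and Nrf2 genes passed by limma or edgeR (*Jafrac1* 1.28 ± 0.25, *GstD1* 0.94 ± 0.37, *Duox* -0.27 ± 0.85), with 16 at an unadjusted p under 0.05. In fits without 1 library *Duox* ran from -1.23 to 0.56 (log2), the last without sucrose library 1. DESeq2 called 4 higher, *Jafrac1* among them, and 1 lower, and limma without Serratia library 3 called *Jafrac1* (0.0497, within a range of 3.88e-05 to 0.987 over its alternatives). Their median of 0.38 was 0.19 without Serratia library 1 and 0.62 without Serratia library 3. The camera adjusted p of 0.013 became an adjusted p of 0.739 with an estimated correlation, 0.0981 without Serratia library 1 and 0.0635 without sucrose library 3. None of 21 heat shock genes passed by limma or edgeR, with 7 higher adjusted over the list alone, 8 at an unadjusted p under 0.05 and 8 higher by DESeq2 (*Hsp83* 1.00 ± 0.21). Their median of 0.42 was 0.11 under quantile normalisation, 0.10 without Serratia library 2, 0.24 without sucrose library 1, 0.15 without sucrose library 2 and 0.13 without the filter. Their camera adjusted p of 0.0252 became an adjusted p of 0.661 with an estimated correlation, 0.271 without Serratia library 2 and 0.0576 without sucrose library 1. Hsp70Aa was not analysed here. None of 29 genes of the unfolded protein response passed by limma or edgeR (*TRAM* 1.05 ± 0.26), with 5 at an unadjusted p under 0.05 and 2 higher by DESeq2. Of these genes 27 had positive fold changes, the median of 0.48 was 0.21 without Serratia library 1 and 0.76 without Serratia library 3, and the adjusted p of 0.00168 was 0.75 with an estimated correlation. None of 22 metal and iron genes passed by limma or edgeR, with 5 higher adjusted over the list alone, 11 at an unadjusted p under 0.05, and 6 higher and 1 lower by DESeq2 (*Mvl* 1.01 ± 0.17, *Zip3* 2.12 ± 0.47). *Mvl*, with a limma adjusted p of 0.0501, passed with an added count of 0.5 (0.0492) or 5 (0.0495), with TMM factors (0.0484) and at a mean of at least 50 (0.0462), and *Zip3* with the replicate block (0.024), within ranges of 2.15e-06 to 0.987 and 0.000115 to 0.461 over their alternatives. The list's median of 0.31 was 0.48 without Serratia library 2, 0.46 without sucrose library 1 and 0.49 with only sucrose library 3 as control, and the adjusted p of 0.00774 was 0.485 with an estimated correlation.

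All 32 oxidative phosphorylation genes had positive fold changes and none passed by limma or edgeR (*Cyt-c-p* 1.34 ± 0.30), with 18 at an unadjusted p under 0.05 and 8 higher by DESeq2. Their median was 0.43, or 0.23 under quantile normalisation, with a camera adjusted p of 1.43e-09 and an adjusted p of 0.661 with an estimated correlation. Of 34 ribosome biogenesis genes 30 had positive fold changes and none passed by limma or edgeR (*Fib* 1.07 ± 0.22), with 19 higher and 3 lower adjusted over the list alone, 23 at an unadjusted p under 0.05, and 13 higher and 2 lower by DESeq2. The median was 0.57, or 0.37 with only sucrose library 3 as control. The camera adjusted p was 3.06e-07, and it was 0.661 with an estimated correlation. Of 86 cytosolic ribosomal protein genes none passed by limma, edgeR or DESeq2, with 1 at an unadjusted p under 0.05 (*RpLP0-like* 0.58 ± 0.19). Their median of 0.14 became -0.07 under quantile normalisation and -0.06 without Serratia library 1, and was 0.30 without Serratia library 2, 0.22 without sucrose library 1, 0.07 without sucrose library 3 and 0.27 with only sucrose library 3 as control. Their camera adjusted p of 0.0312 became an adjusted p of 0.886 with an estimated correlation, 0.173 without Serratia library 1, 0.139 without sucrose library 2 and 0.365 without sucrose library 3. Of 28 autophagy and lysosome genes 26 had negative fold changes and none passed by limma or edgeR (median -0.39, CG8678 -1.03 ± 0.22, *Atg13* 0.76 ± 0.13), with 1 higher and 1 lower adjusted over the list alone, 16 at an unadjusted p under 0.05, and 1 higher and 4 lower by DESeq2, and limma called *Atg13* at a mean of at least 50. Their camera adjusted p was 4.36e-06, and the adjusted p was 0.661 with an estimated correlation. None of 40 lipid genes passed by limma or edgeR (camera adjusted p 0.843, *Seipin* 0.80 ± 0.14), with 1 higher adjusted over the list alone, 10 at an unadjusted p under 0.05, and 3 higher and 2 lower by DESeq2. Nor did 38 cell cycle genes (0.544, *dap* -0.60 ± 0.15), with 2 at an unadjusted p under 0.05 and 1 lower by DESeq2. For 36 actin cytoskeleton genes limma and edgeR called 0 (0.843, *Act5C* 0.75 ± 0.24), with 5 at an unadjusted p under 0.05, and DESeq2 called 1 higher and 1 lower. For 15 peritrophic matrix and mucin genes limma and edgeR called 0 (0.843, *Muc68E* -0.81 ± 0.26), with 2 at an unadjusted p under 0.05, and DESeq2 called 1 higher. The median of 0.11 and mean of -0.13 of the last list differed in sign.

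Of 16 enteroendocrine genes the neuropeptide gene *Mip* (FBgn0036713) rose from 26.3 ± 3.76 to 111 ± 24.9 normalised read counts (SD, n = 3 each, limma adjusted p = 0.0222) and 15 did not pass, with 1 higher adjusted over the list alone, 1 higher by edgeR, and 1 higher and 1 lower by DESeq2. No fit without 1 library called *Mip* (0.0526 without Serratia library 3 to 0.0952 without sucrose library 3), nor did that with the replicate block. The list's camera adjusted p was 0.561, and its median of 0.05 became -0.01 under quantile normalisation. Of 12 stem cell and enteroblast genes 11 had negative fold changes and none passed by limma or edgeR (*zfh2* -0.85 ± 0.20, *HLHmbeta* -0.95 ± 0.25), with 5 lower adjusted over the list alone, 5 at an unadjusted p under 0.05 and 3 lower by DESeq2. Their median was -0.71, or -0.35 without Serratia library 3, and against the sucrose mean Serratia libraries 1, 2 and 3 had medians of -0.378, -0.324 and -0.963. Their camera adjusted p was 0.00127, and the adjusted p was 0.528 with an estimated correlation. Of 10 enterocyte genes 9 had negative fold changes and none passed by limma, edgeR or DESeq2 (*nub* -0.56 ± 0.18), with 2 at an unadjusted p under 0.05. Their median was -0.36, or -0.24 without sucrose library 2, with a camera adjusted p of 0.0278, 0.118 without Serratia library 1 and an adjusted p of 0.661 with an estimated correlation. None of 19 copper cell and acid secretion genes passed by limma or edgeR (*Vha55* 0.50 ± 0.18), with 3 at an unadjusted p under 0.05 and 3 higher by DESeq2. Their median was 0.27, or 0.03 under quantile normalisation and 0.17 with only sucrose library 3 as control, with a camera adjusted p of 0.0296, 0.154 without Serratia library 3, 0.272 without sucrose library 2 and an adjusted p of 0.804 with an estimated correlation. None of 20 visceral muscle genes passed by limma or edgeR (*Act87E* 1.56 ± 0.34), with 9 higher adjusted over the list alone, 11 at an unadjusted p under 0.05 and 9 higher by DESeq2. The median was 0.49, or 0.32 without sucrose library 1, 0.28 under quantile normalisation and 0.29 with only sucrose library 3 as control. For this list the camera adjusted p was 0.000713, with an adjusted p of 0.661 with an estimated correlation.

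Markers of other tissues differed between single libraries. The tubule gene *Uro* stood at 894, 1569 and 95.7 normalised read counts in sucrose libraries 1, 2 and 3 and at 5893, 99.3 and 4383 in Serratia libraries 1, 2 and 3. *Irk3*, another tubule gene, stood at 1409, 829 and 403 in sucrose libraries 1, 2 and 3. In Serratia libraries 1, 2 and 3 it stood at 297, 154.5 and 1320. *Pbprp2*, an odorant-binding protein gene, stood at 612 in Serratia library 1, and the cuticle gene *Lcp1* at 546 in Serratia library 3. Of 17 Malpighian tubule genes *ry* (FBgn0003308), for xanthine dehydrogenase, rose by 1.25 ± 0.18 (log2, SE, limma adjusted p = 0.0343) and 16 did not pass, though no fit without 1 library called it (0.0567 without Serratia library 3 to 0.119 without sucrose library 3), nor did limma without trend, with the replicate block or under scaling by total reads. edgeR and DESeq2 called 1 gene of this list each. The tubule list had a camera adjusted p of 0.198, 0.0239 without Serratia library 2 and 0.0469 without sucrose library 1. None of 15 ovary and germ line genes passed by limma or edgeR (*piwi* -2.56 ± 1.00), with 1 higher adjusted over the list alone, 2 at an unadjusted p under 0.05, and 1 higher and 2 lower by DESeq2. The median was -1.79 (camera adjusted p 0.0701), or -3.19 without sucrose library 3 (6.87e-06) and -0.55 without sucrose library 1 (0.812). With all libraries and an estimated correlation the camera adjusted p was 0.804. With only sucrose library 3 as control the median reversed to 0.96. All 10 hemocyte genes had positive fold changes and none passed by limma, edgeR or DESeq2, with 0 at an unadjusted p under 0.05 (median 0.67, *Sr-CI* 0.71 ± 0.33). Their camera adjusted p of 0.0296 became an adjusted p of 0.667 with an estimated correlation, 0.188 without Serratia library 3, 0.0545 without sucrose library 2 and 0.136 without sucrose library 3. None of 13 fat body genes passed by limma or edgeR (0.235, and 0.0448 without Serratia library 1), with 2 at an unadjusted p under 0.05 and 1 higher by DESeq2. Nor did any of 17 cuticle protein genes by limma, edgeR or DESeq2, with 1 at an unadjusted p under 0.05 (0.159, 0.0333 without Serratia library 1 and 0.0484 without sucrose library 2). None passed by these 3 tools of 9 trachea genes (camera adjusted p 0.426, 2 at an unadjusted p under 0.05) or 7 neuron and glia genes (0.561, 0 at an unadjusted p under 0.05). Of 30 odorant-binding protein and chemoreceptor genes limma and edgeR called 0 (0.843), with 2 at an unadjusted p under 0.05, and DESeq2 called 1 higher.

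**Figure D2:**
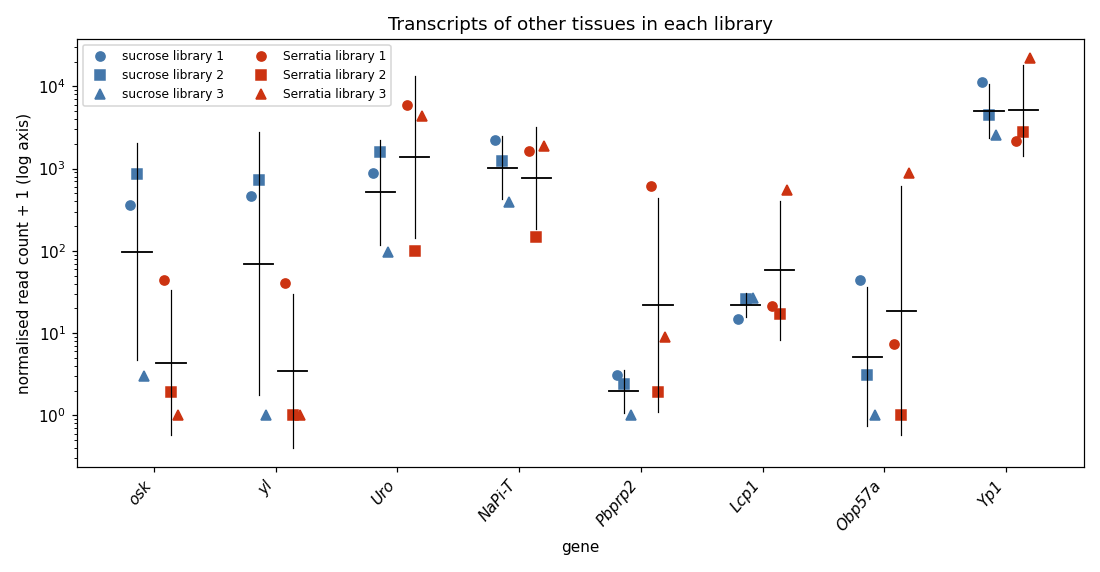
Normalised read counts plus 1 (log axis) of 8 transcripts of other tissues in each of the 6 libraries, chosen after the values were seen. Horizontal bars mark the mean and vertical lines the SD, both on the log2 scale, and *Uro* lies at 5893 and 4383 in Serratia libraries 1 and 3 but at 99.3 in Serratia library 2.

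Of the 38 lists, 18 passed camera with the preset correlation of 0.01, 13 higher and 5 lower. With an estimated correlation camera called 0 lists, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.485, and the directional test of fry called 1, that of sugar and insulin genes (adjusted p = 0.0406).

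**Figure D3:**
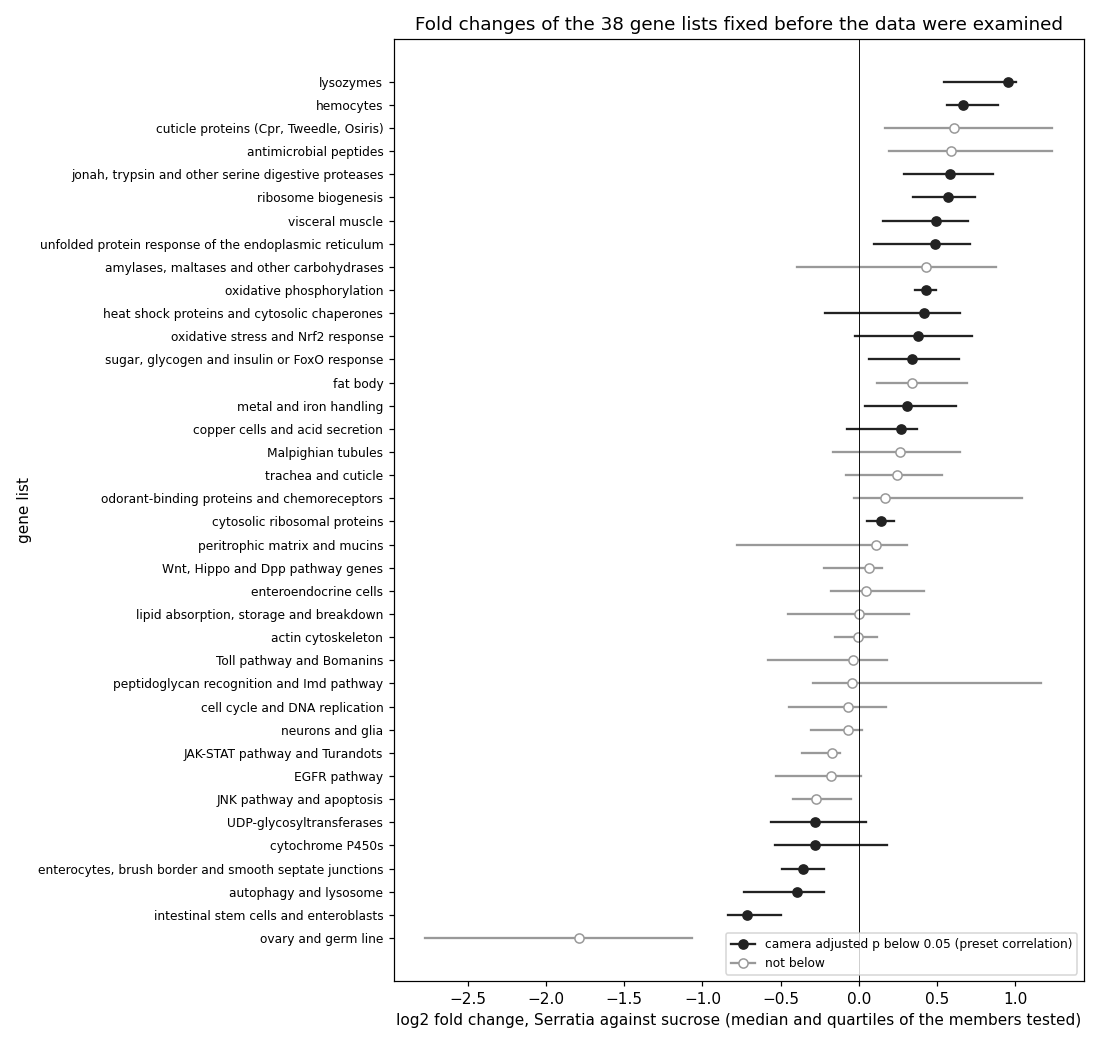
Median log2 fold change (points) with quartiles (lines) of the members tested in each of the 38 gene lists, Serratia against sucrose. Of these, 18 passed camera with the preset correlation and 0 with an estimated correlation, and the medians of 2 lists change sign under quantile normalisation, those of enteroendocrine cells (0.05) and ribosomal proteins (0.14). Under scaling by total reads 7 change sign with its shift included and 0 with the shift removed.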

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

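Scaling by total reads and the fit with only sucrose library 3, whose lone control is assumed to vary like the other group, were chosen after seeing the data. All 88 genes kept their sign in every alternative. Where libraries are left out or another count is added this is fixed in advance, since the groups do not overlap in these genes. It is also fixed for another filter, limma without trend or with robust variances, and the replicate block, which leave these fold changes unchanged. For single genes named, 2430 values stayed on the same side of the threshold, within the main SE where past it in neither fit. A further 133, past it in neither fit, moved by more than that SE. Of the others 332 were no longer past it, 72 newly past it and 0 past it in either fit reversed. For lists, 633 were on the same side, 27 no longer past, 21 newly past and 3 past it in either fit reversed. Sign changes of values past it in neither fit were not counted as reversed. Without 1 library *Duox* ran from -1.23 to 0.56 and *Cp15* from -3.12 to 2.21 (log2). The cause was not tested except where fewer libraries were used. Counting limits low genes.

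The replicate number as a block gave 27 genes, 26 higher and 1 lower, 27 of them at least 2-fold, with 23 of the 88 kept. The labels do not say that equal numbers pair the libraries. Correlations of deviations between libraries of equal number were 0.0786, 0.0794 and -0.259 across genes, which cannot exclude a pairing. DESeq2 gave 855 genes, 525 higher, 330 lower and 336 at least 2-fold. limma without trend gave 41 genes, 34 higher, 7 lower and 41 at least 2-fold. Quantile normalisation gave 24 lower. Scaling by total reads gave 58 genes, 39 of them higher. With only sucrose library 3 there was 1 gene, 1 higher, 0 lower and 1 at least 2-fold by limma, with 407 at an unadjusted p under 0.05, while the median log2 fold changes of the 73 higher and 15 lower genes, 1.82 and -1.36 with all libraries, were 1.79 and -1.34, near by selection since this library was used to call them. Leaving out 1 library gave 17 to 88 genes, 15 to 57 higher, 0 to 31 lower (1198 at an unadjusted p under 0.05 where 0 were lower) and 17 to 86 at least 2-fold. Lists past the threshold were 0 by camera with an estimated correlation (3 at an unadjusted p under 0.05), 1 by the directional test of fry, and 15 to 19 without 1 library.

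List medians (log2) follow where a call changed. Under scaling by total reads, with its shift of -0.27 included, these were 0.354 for antimicrobial peptides, 0.0053 for copper cells, 0.0713 for fat body, -0.003 for Malpighian tubules, -0.549 for cytochrome P450s, -0.128 for ribosomal proteins and 0.368 for cuticle proteins. With only sucrose library 3 they were 1.93 for antimicrobial peptides, 0.170 for copper cells, 0.997 for fat body, 0.654 for Malpighian tubules, 0.958 for ovary (reversed), -0.151 for cytochrome P450s and 1.10 for cuticle proteins. Under quantile normalisation they were 0.0327 for copper cells, 0.114 for heat shock and -0.0673 for ribosomal proteins (reversed). Without the filter they were 0.616 for hemocytes, -1.79 for ovary and -0.196 for cytochrome P450s. At a mean of at least 50 they were -0.353 for JNK and 0.588 for hemocytes. Ovary had -1.59 at an added count of 5 and -1.79 with the block.

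Without 1 library the medians ran from -0.477 to -0.0427 for JAK-STAT, -0.389 to -0.171 for JNK, -0.416 to -0.0533 for EGFR, -0.461 to -0.242 for enterocytes, 0.220 to 0.351 for copper cells, 0.451 to 0.892 for hemocytes, -0.440 to 0.746 for fat body, -0.167 to 0.617 for Malpighian tubules, -3.19 to -0.554 for ovary, 0.188 to 0.616 for oxidative stress, -0.342 to -0.180 for cytochrome P450s, 0.0986 to 0.502 for heat shock, -0.055 to 0.304 for ribosomal proteins, 0.217 to 1.04 for cuticle proteins and -0.264 to -0.203 for UDP-glycosyltransferases.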

Other observations

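The tests of the 15 lower genes, of the 8 most risen genes and of the splits were chosen after the results were seen, and the gene lists of the next paragraph after called genes were seen, with each hypothesis tested on members not called.

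In lists chosen after called genes were seen, and so no independent evidence of their direction, 5 of 25 nucleic acid and nucleoside genes, 4 of 20 amino acid transporter genes and 3 of 16 genes of serine, glycine, one-carbon and purine synthesis rose, 3 of 40 DNA repair genes fell, and the others did not pass. The pyrimidine breakdown gene *su(r)* (FBgn0086450) rose from 2681 ± 641 to 14037 ± 1281 normalised read counts (SD, n = 3 each, limma adjusted p = 0.00611), CG8083 (FBgn0025709) by 2.24 ± 0.19 (log2, SE), the adenosine deaminase gene *Adgf-A* (FBgn0036752) by 1.95 ± 0.16 and the amino acid transporter gene CG8785 (FBgn0033760) by 1.84 ± 0.16. *DNaseII* rose by 2.73, *CG3011* by 1.41, *ade2*, of purine synthesis, by 1.34 and the transporter genes CG1139, CG4991 and *slif* by 2.26, 1.82 and 1.37. Without sucrose library 2 the adjusted p of *DNaseII*, CG3011, *ade2*, CG4991 and *slif* was 0.0879, 0.0568, 0.0851, 0.061 and 0.0851, without Serratia library 2 it was 0.0949, 0.0533, 0.0737, 0.0558 and 0.109, and that of CG1139, called only without sucrose library 2, was up to 0.171, without sucrose library 1. No fit without 1 library called *slif* or the DNA repair gene CG7922 (adjusted p 0.0587 to 0.171 for CG7922). The call of CG7922 also ended by limma without trend (0.0705) and with the replicate block (0.12). In fits without sucrose library 1 or sucrose library 3 the calls of *DNaseII* (0.106 and 0.0654), CG3011 (0.0665 and 0.0603), *ade2* (0.0676 and 0.0906) and *slif* (0.12 and 0.0964) ended too. The replicate block ended the calls of *DNaseII*, *ade2*, *slif*, CG1139, CG3011 and CG4991, scaling by total reads those of CG1139, *ade2* and *slif*, limma without trend those of CG1139 and *slif*, limma-voom that of *DNaseII* and edgeR that of CG1139.

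The hypothesis that serine, glycine, one-carbon and purine synthesis genes rose as a set was tested on 13 members not called, with a median of 0.51 (log2) and a camera p of 0.0238 with an estimated correlation. For DNA repair genes, expected lower, 37 members not called had a median of -0.30, 2 of them positive, and a p of 0.0467. For 16 amino acid transporter genes p was 0.272 (median 0.19), and for 20 nucleic acid and nucleoside genes 0.64 (median 0.13), which leaves these hypotheses open. Adjusted over the 4 tests the first 2 had 0.0934 and did not pass. Of 4 further lists with 0 genes called by limma and edgeR, 7 chaperonin genes had a median of 0.52 (p = 0.139 by camera with an estimated correlation), 72 mitochondrial ribosomal protein genes 0.32 (p = 0.5), 21 aminoacyl-tRNA synthetase genes 0.21 (p = 0.392) and 33 proteasome genes 0.03 (p = 0.909), or -0.05 under quantile normalisation. At an unadjusted p under 0.05 there were 5, 2, 3 and 1 of these genes, and DESeq2 called 0, 0, 2 and 0.

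The 15 lower genes were weighed against ovarian tissue in sucrose libraries 1 and 2, where *osk* and *yl* were high, against 2.0 and 0 normalised read counts in sucrose library 3. The median of the Serratia mean minus sucrose library 3 was -1.342 (SD 1.075 over the 15 genes, log2). The calling of these genes fixes such a value, because with sucrose library 3 set to the Serratia mean, as carry-over alone would have it, limma called 0 of the 15, with 7 at an unadjusted p under 0.05 (other tools were not run on these values). Over 40 DNA repair genes, among them the lower genes *spel1*, *Fancl* and CG7922, the median was -0.285 (SD 0.48 over the genes), within that SD of the bound of -0.1. Of these genes 37 were not called, so calling did not fix their values. The SD over genes does not measure the error of the median, and the value rests on a single control library, so this test cannot decide. Ovarian carry-over and a response to *Serratia* cannot be told apart for the 15 lower genes, since a single control library lacks the ovary transcripts and it was used to call them.

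The 8 most risen genes were weighed against antenna, tubule or cuticle carried into Serratia libraries 1 and 3. The mean of Serratia libraries 1 and 3 over Serratia library 2 had a median log2 ratio of 0.182 (SD 0.574 over the 8 genes), against at least 3.567 for *Uro*, *NaPi-T*, *Pbprp2*, *Lcp1* and *Obp57a*. The tubule gene *Irk3*, at 297, 154.5 and 1320 normalised read counts in Serratia libraries 1, 2 and 3, was not in this comparison. The calling of the 8 genes limits this ratio too, because with Serratia library 2 set 3.567 below libraries 1 and 3 limma called 0 of the 8, with 8 at an unadjusted p under 0.05 (other tools were not run on these values). Carried-over tissue and a response to *Serratia* therefore cannot be told apart for these genes. The ratio of Serratia library 1 to 3 was 0.97 for CG13947, 3.66 to 4.27 for *lcs*, CG32984, CG8708 and *Est-6*, and 12 for *LysP*.

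The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 88 genes, 73 higher, 15 lower and 81 at least 2-fold, each in 1 of 10 splits, and the highest of the other splits gave 0 by limma and 0 by edgeR, with 60 to 633 genes at an unadjusted p under 0.05. For lists 2 of 10 splits gave as many, with 18 in the real split and 20 in that of sucrose libraries 1 and 3 with Serratia library 2. All the other splits gave 6 to 20 lists by camera with the preset correlation, though limma called 0 genes in each.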
